A study of Neotoma bryanti and Neotoma lepida with 12 samples.

How the data were processed

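Liver RNA of 12 woodrats was hybridised to one-colour custom arrays, 1 array per animal. Per the labels' protocols, tissue was kept in RNAlater, RNA was extracted with RNAqueous, and Cy3 labelling used a one-colour Quick Amp kit. Per the submitters' processing notes, images were read with Agilent Feature Extraction 10.5.1.1. The deposited table held log2 values for 6986 rows, as judged from their range. The medians of all rows were equal on the 12 arrays at 10.55, so the authors' values had been aligned on the median. The background correction and any further step were not given in the sources used here. Scanner files, spot flags, slide positions and scan order were not analysed here, so probes could not be called above background from the image.

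The 60 control rows were left out of all tests and used only to describe the arrays, which left 6926 probes. There were 9 missing values in 8 probes, and they stayed missing. No pair of arrays held identical values. The number of arrays limits the precision. Replicate numbers follow the order of the samples and pair no animals. The labels name separate animals, so p-values measure the spread between animals within a group.

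Choices stated here were made before the data were examined unless said otherwise. The 75th percentiles of the deposited arrays differed by 0.150 log2 units, over the limit of 0.1, so each array's 75th percentile was subtracted and the mean percentile added back. Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 model of the 3 groups, with contrasts for N. lepida against the mean of the N. bryanti populations and for each pair of groups. Sex was tested in a model with population and sex. P-values were adjusted by Benjamini-Hochberg over all probes within each comparison, with a threshold of 0.05. Group distances were 1 minus the Pearson correlation of arrays, tested by exact permutation. Confidence intervals of shares were exact binomial, and cover counting only.

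The rule for named genes called for the largest differences past the threshold whose animals did not overlap between groups, with gene lists of liver pathways and cell types beside them. It stated that, with no names paired to the probes, at most 2 probes that were higher and 2 that were lower would be given per comparison by identifier. The files do not pair names, so this fallback was used, and the pathway and cell type lists, their tests and gene-level alternatives were not run. The sex probe was named after its values were seen, since the non-overlap rule selected none. Several probes may measure 1 gene, so counts of probes are not counts of genes.

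The low ends of the arrays differed, and a common floor was added after this had been seen: the highest of the 12 arrays' 25th percentiles, 7.48 log2 units, to which lower values were raised. A probe whose group lay wholly below this floor has only a bound there, given as "at least N-fold" against the floor. No fold was given where both groups lay below it.

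The position of an animal was its slope on the difference between N. lepida and Caspers Wilderness, over probes at least 2-fold apart. Both outer groups were divided into pairs of animals in all 36 ways, with one pair of each group for the difference and the remaining animals for the baseline and the slopes. Each Caspers Wilderness animal was measured against its partner, so the mean of that group is 0 by construction. The test, added after the slopes had been seen, recomputed the Palm Springs slope for all 70 ways to assign the 8 N. bryanti arrays to the 2 populations.

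The tests were tried on simulated data made from the real probes' levels and spreads, with 50 probes changed at each of 4 sizes among 6918. For the species comparison, 24% of changes of 0.5 log2 units, 68% of 1, 92% of 2 and 94% of 3 were recovered. For N. lepida against Caspers Wilderness the shares were 14%, 56%, 80% and 92%. For N. lepida against Palm Springs they were 24%, 50%, 84% and 90%, and for the N. bryanti populations 18%, 52%, 90% and 90%. For sex they were 26%, 68%, 86% and 92%. False calls numbered between 4 and 9 per comparison. The adjusted threshold depends on how many probes change, and 25.8% of probes passed in the real species comparison. The recovery shares therefore hold for the simulated setting and need not hold for the real comparisons.

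Alternatives were quantile normalization, median centring, leaving out dim probes, eBayes with trend and robust options, sex as a covariate, array weights, pairwise fits, a 2-fold minimum, males only and leaving out each animal. The common floor and a fit without the 3 arrays of raised low end (Caspers Wilderness replicate 3, N. lepida replicates 3 and 4) were added after the data had been seen.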

Results

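Liver gene expression was measured in 12 woodrats (genus Neotoma), herbivorous rodents of western North America, with a one-colour oligonucleotide array carrying 6926 probes. Each array held the liver RNA of 1 animal. The animals formed 3 groups of 4: Neotoma bryanti from Caspers Wilderness (1 female and 3 males), N. bryanti from Palm Springs (2 females and 2 males) and N. lepida from Lytle Ranch (2 females and 2 males). All animals ate a rabbit chow diet, and their intake was followed for 10 days before the liver was taken. Of the probes, 6286 carried custom identifiers (CUST, in 4 families) and 640 carried identifiers of the array maker's catalogue type (A_). The files do not pair gene names with the probes, so results are given by probe identifier and by probe family. The 12 arrays had between 4928 and 5194 probes above a common floor of 7.48 log2 units. That floor is the highest of their 25th percentiles, so similar counts follow largely from its definition. The 75th percentiles of the deposited arrays separated the species. They were at most 12.716 in N. lepida arrays and at least 12.734 in N. bryanti arrays. Aligning the 75th percentiles therefore raised every N. lepida array relative to every N. bryanti array. The low ends of the arrays also differed. The 5th percentile was 5.34 in Caspers Wilderness replicate 3 and between 2.03 and 2.37 in the other Caspers Wilderness arrays. It was 3.30 and 4.05 in N. lepida replicates 3 and 4.

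**Figure D1:**
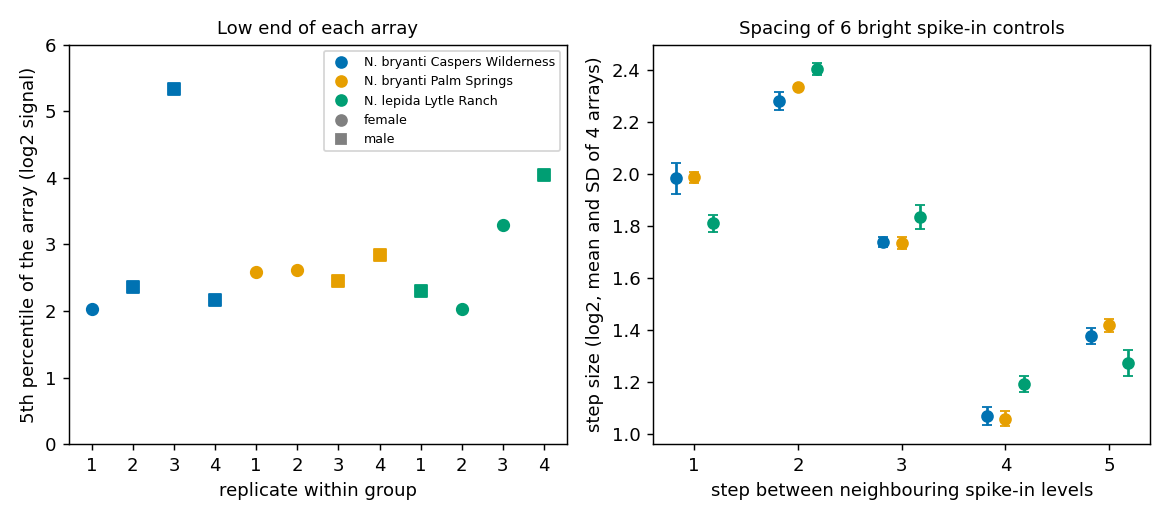
The left panel shows the 5th percentile of each array in log2 signal, with colours for groups and shapes for sex, and Caspers Wilderness replicate 3 is highest at 5.34. The right panel shows the log2 step between neighbouring levels of 6 bright spike-in controls as mean and SD of 4 arrays per group, and the N. lepida arrays lie apart from both N. bryanti groups on all 5 steps.

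The first question was how far the 3 groups stood apart as a whole. Each pair of groups was further apart than animals within a group. The mean correlation distance between N. lepida and Caspers Wilderness arrays was 0.0421, against 0.0186 within these groups. Between N. lepida and Palm Springs it was 0.0287 against 0.0152, and between Palm Springs and Caspers Wilderness it was 0.0322 against 0.0189. Each of these differences gave an exact permutation p of 0.0286, the smallest that the 35 splits of 8 arrays can give. The Palm Springs arrays lay closer to N. lepida (0.0287 ± 0.0019, SD, n = 4) than the Caspers Wilderness arrays did (0.0421 ± 0.0088, SD, n = 4; two-sided exact permutation p = 0.0286). Without Caspers Wilderness replicate 3, the distance from Caspers Wilderness was 0.0378 to N. lepida and 0.0267 to Palm Springs. Palm Springs then lay nearer to Caspers Wilderness than to N. lepida.

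With all values below the common floor raised to it, the first principal component held 42.6% of the variance and placed Caspers Wilderness at -30.7 ± 2.4, Palm Springs at 0.311 ± 1.85 and N. lepida at 30.4 ± 4.47 (SD, n = 4 each). The second component held 18.4% and set Palm Springs (-22.8 ± 6.07) apart from Caspers Wilderness (11.4 ± 1.45) and N. lepida (11.4 ± 2.52). The common floor was chosen after the low ends had been seen. Without it, the first component held 29.9% (Caspers Wilderness -39.8 ± 11.9, Palm Springs 2.70 ± 3.88, N. lepida 37.1 ± 2.72; SD, n = 4 each). The second then held 27.6% and had Caspers Wilderness replicate 3 at -78.5, and Palm Springs stood apart on the third (14.4%; 29.2 ± 4.51 against -14.7 ± 15.2 and -14.4 ± 4.96; SD, n = 4 each).

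**Figure D2:**
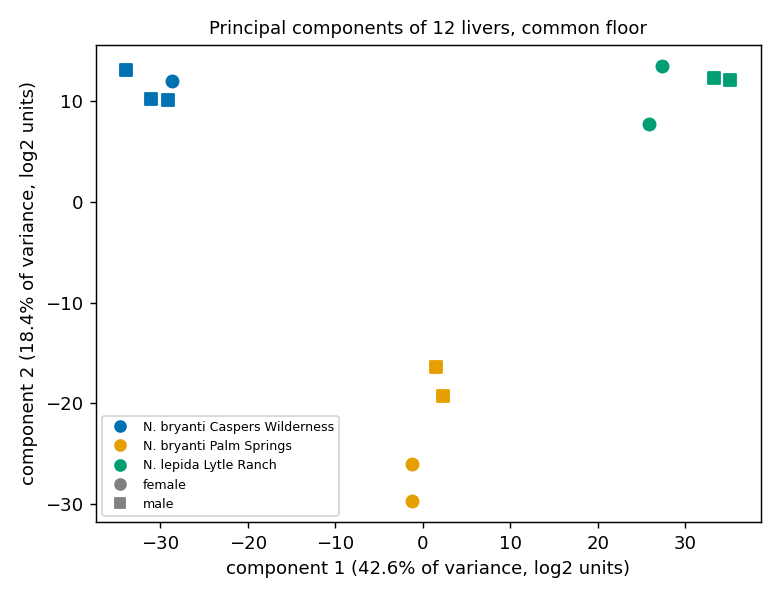
Each point is 1 liver, plotted by its scores on components 1 and 2 (42.6% and 18.4% of the variance, log2 units) after values below the common floor were raised to it. Palm Springs animals lie between the other groups on component 1, with a mean of 0.311, and apart from both on component 2.

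Species were compared by setting N. lepida against the mean of the 2 N. bryanti populations. Of 6926 probes, 1787 passed the threshold, 845 higher and 942 lower in N. lepida. Among these, 525 differed at least 2-fold, 127 at least 4-fold and 20 at least 16-fold. The probe CUST_1990_PI426384047 was higher in N. lepida by 9.77 ± 1.82 log2 units (SE; limma adjusted p = 0.00364), at 17.11 ± 0.25 in N. lepida (SD, n = 4) and 7.35 ± 3.82 in N. bryanti (SD, n = 8). CUST_60_PI426383273 was higher by 8.35 ± 1.51 (limma adjusted p = 0.00318). For both probes, Palm Springs replicate 4 lay near the N. lepida level, at 16.38 and 17.07, and without it the differences were 11.12 and 9.46. With the common floor they were 8.49 and 8.15. CUST_347_PI426386924 was at least 26.8-fold lower in N. lepida (limma adjusted p = 0.00141; -5.07 with the common floor), a bound that was 56.9-fold without Palm Springs replicate 3 and 19.2-fold without replicate 1, and CUST_126_PI426384047 was at least 7.75-fold lower (limma adjusted p = 5.54e-05). With the 7 males only, 3 of these 4 calls were lost. The differences were 8.45 ± 3.04 at CUST_1990_PI426384047 and 7.54 ± 2.47 at CUST_60_PI426383273 (SE; limma adjusted p = 0.132 and 0.109), so their errors grew more than their sizes fell. At CUST_347_PI426386924 the bound was 11.8-fold (0.073). The majority direction depended on the scaling, on dim probes and on a single array. The share of higher calls was 47.3%, and 36.4% with arrays centred on their medians (696 higher and 1216 lower). It was 50.6% with quantile normalization (923 and 900), 52.9% without the dimmest 25% of probes (941 and 837) and 54.1% with the common floor (956 and 812). Leaving out Caspers Wilderness replicate 3 alone gave 1027 higher and 980 lower. Without the 3 arrays of raised low end, 807 probes passed.

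**Figure D3:**
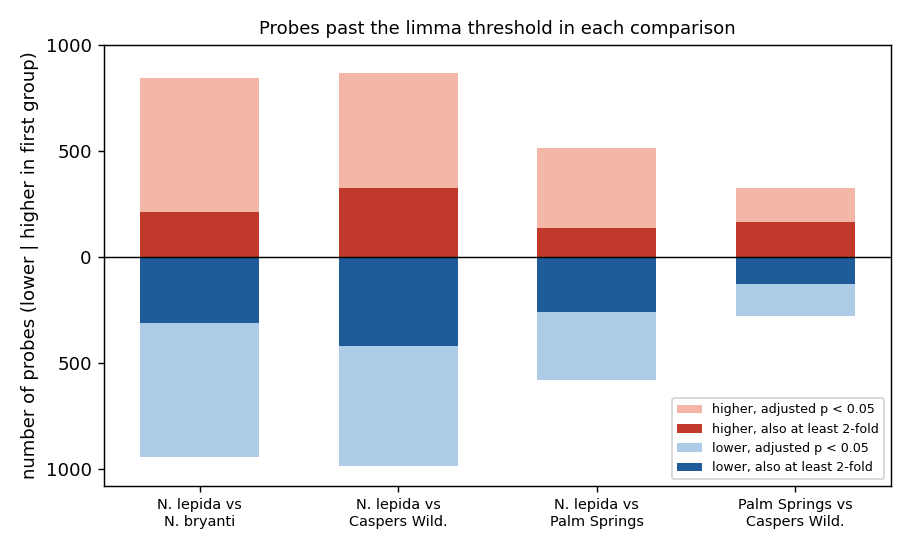
Bars give the number of probes past the limma threshold, higher (up) and lower (down) in the first group named, with the darker part for probes that also differed at least 2-fold. Palm Springs against Caspers Wilderness has the fewest, 323 higher and 276 lower.

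The direction of the species difference depended on the probe family. Of the called catalogue probes, 15 were higher and 101 lower in N. lepida, so 87.1% were lower (95% exact binomial interval 79.6 to 92.6). Of the called custom probes, 830 were higher and 841 lower (50.3% lower), an odds ratio of 6.64 (Fisher's exact test, adjusted p = 7.29e-15, 8 tests; probes are not independent replicates). The catalogue share was 91.5% with median centring and 70.3% with quantile normalization, against 61.4% and 47.6% of custom probes. In the custom family PI426386924, 85 probes were higher and 190 lower in N. lepida. In that family, 88 were higher and 38 lower in Palm Springs than in Caspers Wilderness. The difference between the N. bryanti populations had no family split past the threshold for catalogue probes (odds ratio 1.83, Fisher's exact test, adjusted p = 0.083).

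Spike-in controls, RNA added in the laboratory and supplied by no animal, also separated the species. The spacing of 6 bright controls gave 5 steps, and on 5 of 5 the 4 N. lepida arrays lay outside the range of the 8 N. bryanti arrays (exact permutation p = 0.00202 for each, the smallest that reassigning the 12 arrays can give). The steps differed by between -0.17 and 0.13 log2 units. Neighbouring steps share a control, so the 5 steps are not independent. Between Palm Springs and Caspers Wilderness, 1 of the 5 steps separated all arrays (2.33 ± 0.0068 against 2.28 ± 0.035, SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.143). That p is the smallest that 4 against 4 arrays can give, so a single separated step cannot pass after adjustment over the 5 steps. Batch and species cannot be told apart in the comparisons with N. lepida.

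N. lepida and Caspers Wilderness differed at 1852 probes, the most of the 3 pairs of groups, with 867 higher and 985 lower in N. lepida, 748 of them at least 2-fold and 225 at least 4-fold. CUST_1990_PI426384047 was higher in N. lepida by 10.67 ± 2.11 (SE; limma adjusted p = 0.00436), and CUST_870_PI426386924 by 10.66 ± 2.38 (limma adjusted p = 0.00818). At each probe 3 of the 4 Caspers Wilderness animals lay below the common floor, so the size depends on the low end: with that floor the differences were 9.57 and 8.06. The CUST_870_PI426386924 difference was 11.89 without Caspers Wilderness replicate 2 and 9.59 without replicate 4, and its call was lost without the 3 arrays of raised low end (10.97 ± 3.43, SE; limma adjusted p = 0.0698). The CUST_1990_PI426384047 call was lost with males only (10.51 ± 3.29, SE; 0.0929). Neither loss came with a clear change in size, and both came with fewer arrays and larger errors. CUST_347_PI426386924 was at least 46.9-fold lower (limma adjusted p = 0.00159), at 13.03 ± 0.19 in Caspers Wilderness (SD, n = 4). A_43_P15847 was at least 9.78-fold lower (limma adjusted p = 0.00231), and its Palm Springs animals divided, with 9.42 and 9.73 in replicates 2 and 4 and 3.71 and 3.85 in replicates 1 and 3. With median centring, 736 probes were higher and 1209 lower (37.8% higher in place of 46.8%). The share was 48.0% with quantile normalization, 50.6% without the dimmest 25% of probes and 51.1% with the common floor. Leaving out Caspers Wilderness replicate 3 alone gave 868 higher and 782 lower. Without the 3 arrays of raised low end, 903 probes passed (51.4% higher).

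N. lepida and Palm Springs differed at 1095 probes, 515 higher and 580 lower in N. lepida. Of these, 399 differed at least 2-fold, with a less even split of 138 higher and 261 lower. CUST_48_PI426386924 was at least 21.3-fold higher in N. lepida (limma adjusted p = 0.00175), with 11.89 ± 0.18 against 3.13 ± 0.52 (SD, n = 4 each). CUST_1990_PI426384047 was higher by 8.86 ± 2.11 (SE; limma adjusted p = 0.0194), with 3 Palm Springs animals below the common floor and replicate 4 at 16.38. This difference was 7.41 with the common floor, 11.58 without Palm Springs replicate 4, and 7.68 without replicate 1 or replicate 3. The call was lost without Palm Springs replicate 2 (limma adjusted p = 0.0529), without the 3 arrays of raised low end (8.82 ± 2.87, SE; 0.0943) and with males only (6.39 ± 3.61, SE; 0.345). CUST_347_PI426386924 was at least 15.3-fold lower (limma adjusted p = 0.00794), although Palm Springs replicate 3 was at 4.89 and the other Palm Springs animals were between 13.20 and 14.29. The bound was 68.9-fold without that animal and 7.85-fold without Palm Springs replicate 1, and the difference with the common floor was -4.58. With males only the CUST_48_PI426386924 and CUST_347_PI426386924 calls were also lost, with bounds of 19.4-fold and 2.96-fold (limma adjusted p = 0.0918 and 0.239). CUST_126_PI426384047 was at least 8.27-fold lower (limma adjusted p = 0.000281). The majority direction turned here too. Median centring gave 400 higher and 722 lower (35.7% higher in place of 47.0%), and the fit without the 3 arrays of raised low end 177 and 401 (30.6%). Quantile normalization gave 572 and 501 (53.3%), leaving out the dimmest 25% 634 and 514 (55.2%) and the common floor 653 and 492 (57.0%). Leaving out Palm Springs replicate 4 alone gave 393 higher and 360 lower. The count was 644 without Palm Springs replicate 2, 664 without N. lepida replicate 1, 686 without N. lepida replicate 4 and 578 without the 3 arrays of raised low end.

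The 2 N. bryanti populations differed at 599 probes, 323 higher and 276 lower in Palm Springs, of which 292 differed at least 2-fold and 109 at least 4-fold. Without Caspers Wilderness replicate 3 the split was 396 higher and 202 lower, and without the 3 arrays of raised low end it was 481 and 204 (70.2% higher in place of 53.9%). CUST_340_PI426383273 was at least 46.7-fold higher in Palm Springs (limma adjusted p = 4.1e-06). Its level was 13.03 ± 0.48 in Palm Springs and 4.15 ± 1.23 in Caspers Wilderness (SD, n = 4 each), and the N. lepida animals lay between 12.93 and 13.07. CUST_171_PI426386924 was at least 2.50-fold higher (limma adjusted p = 0.0434), with 13.57 and 11.46 in the Palm Springs males and 5.12 and 5.06 in the females. This call was lost with the common floor (limma adjusted p = 0.167), in a fit of these 2 groups alone (0.108), without the 3 arrays of raised low end (0.0551) and on leaving out any 1 of 9 of the 12 animals (0.0575 to 0.104). Without Palm Springs replicate 3 the mean fell below the floor, so no bound remained. The bound was 5.94-fold without Palm Springs replicate 2 and 32.8-fold with males only. The call was kept with males only (limma adjusted p = 0.0287) and with sex as a covariate (0.0156). CUST_203_PI426384047 was at least 24.7-fold lower in Palm Springs (limma adjusted p = 0.000718), and CUST_48_PI426386924 at least 5.01-fold lower (limma adjusted p = 0.00881). At CUST_48_PI426386924, Caspers Wilderness replicate 3 was at 5.05 and the others between 10.71 and 12.64. The bound there was 15.0-fold without replicate 3 and 2.60-fold without replicate 1, and the difference with the common floor was -2.93. The call was lost with males only, with a bound of 2.60-fold (limma adjusted p = 0.254). At CUST_203_PI426384047 and CUST_48_PI426386924 N. lepida was at a high level, 11.39 ± 0.56 and 11.89 ± 0.18 (SD, n = 4). The count was 393 without Caspers Wilderness replicate 4, 375 without Palm Springs replicate 2 and 980 with array weights.

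**Figure D4:**
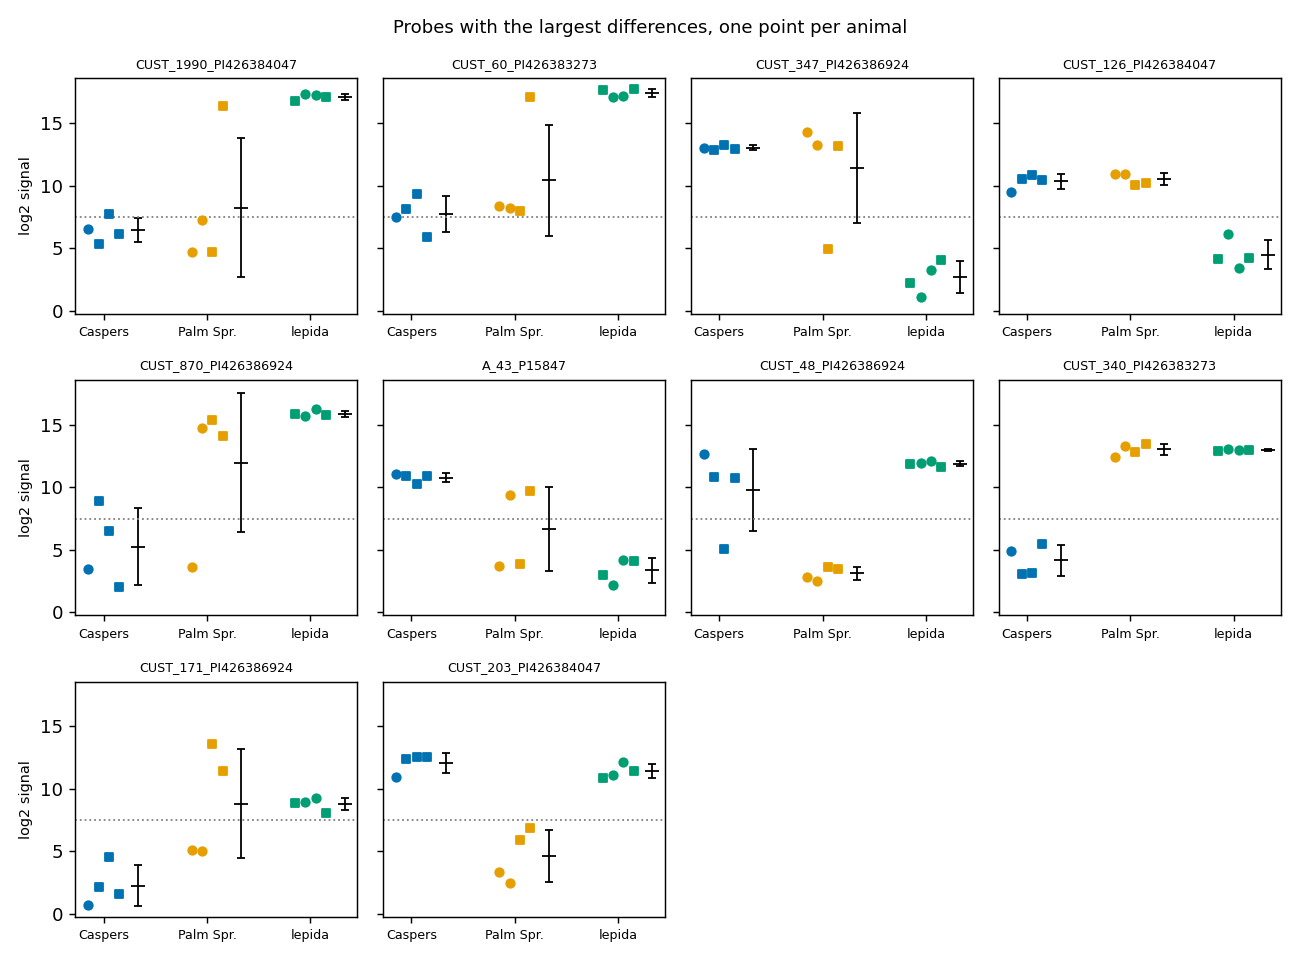
Each point is the log2 signal of 1 animal at a named probe, by group, with bars for the group mean and SD (n = 4) and a dotted line at the common floor of 7.48. At several probes the Palm Springs animals divide between levels, as at A_43_P15847, with values near 9.42 and 3.71.

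Differences from Caspers Wilderness, and differences from N. lepida, were each shared in part by the remaining groups. Of the probes called between Caspers Wilderness and both other groups, 225 were higher in both groups and 170 lower in both, against 40.4 and 39.3 for independent lists, and 10 went opposite ways. The correlation of the differences across probes was 0.634, and 0.494 in simulations of unchanged groups with the same shared arrays. The covariance was 0.447 against 0.0903 simulated. With the Caspers Wilderness arrays split so that 2 served each difference, the means over 6 splits were 100.2 probes higher in both, 60 lower in both (13.1 and 9.43 for independent lists), a correlation of 0.392 and a covariance of 0.324. Differences from N. lepida were shared by more probes, but from longer lists (1852 and 1095 calls, against 1852 and 599 for Caspers Wilderness). N. lepida was higher than both N. bryanti groups at 337 and lower than both at 373 (64.5 and 82.5 for independent lists), and 8 went opposite ways. The correlation there was 0.623 (0.495 simulated) and the covariance 0.434 (0.0909 simulated). With the N. lepida arrays split, the means were 111.3 probes higher and 141.2 lower in N. lepida (18.6 and 24.0 for independent lists), a correlation of 0.487 and a covariance of 0.369. Palm Springs was higher than both other groups, or lower than both, at 110 probes. A group with differences of its own shares them in this way, so counts above those for independent lists set no group apart. Probes are not independent replicates.

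The position of each Palm Springs animal along the difference from Caspers Wilderness to N. lepida was then measured, a test chosen after the components had been seen. It was the slope over probes that differed at least 2-fold, with separate arrays on each side. The slope was 0.441 ± 0.038 in Palm Springs and 0.848 ± 0.059 in N. lepida (SD, n = 4 each). The Caspers Wilderness mean was fixed at 0 by construction, with an SD of 0.050 between its 4 animals. When the 8 N. bryanti arrays were regrouped and the slope recomputed, a test added after the slopes had been seen, 1 of 70 assignments, the real one, lay as far from 0 (two-sided exact permutation p = 0.0143, the smallest possible). Mixed assignments gave between -0.209 and 0.209, and exchanging the 2 population names gave 0.0074. If Palm Springs lay on a straight line between the other groups, that exchange would give a negative value. The slope alone does not place Palm Springs on that line. A group off it, equally far from both others, would also have an intermediate slope. Relative to N. lepida, Palm Springs stood at 0.520 ± 0.044 (SD, n = 4). Without the common floor the slope was 0.300 ± 0.044 in Palm Springs, and Caspers Wilderness replicate 3 was at 0.331. Single probes were not all intermediate. With the common floor, 154 of the probes called between the outer groups stayed at least 4-fold apart, fewer than the 225 without it. Of these, 42 had Palm Springs means near Caspers Wilderness (under 0.25 of the way to N. lepida), 50 near N. lepida (0.75 or more) and 62 between. Of the 84 such probes higher in N. lepida, 40 were near N. lepida and 10 near Caspers Wilderness. Of the 70 lower in N. lepida, 10 and 32 were. These counts use group means, so a probe at which the Palm Springs animals divide between the outer levels can count as between.

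**Figure D5:**
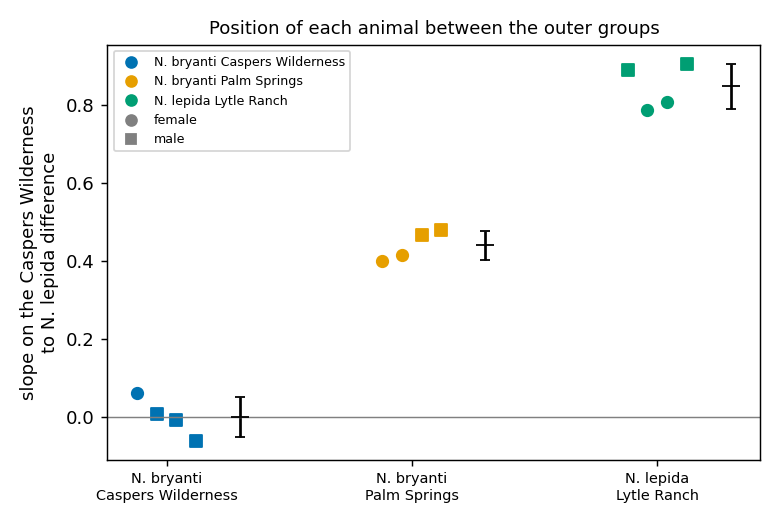
Each point is the slope of 1 animal on the difference from Caspers Wilderness (0) to N. lepida, with the group mean and SD (n = 4) beside the points and shapes for sex. The Caspers Wilderness mean is 0 by construction. The Palm Springs animals lie between 0.401 and 0.479, above all Caspers Wilderness animals and below all N. lepida animals.

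Males and females were compared within populations. One probe, CUST_295_PI426395977, passed the threshold and was higher in males by 1.38 ± 0.14 log2 units (SE, 2.61-fold; limma adjusted p = 0.0129; 7 males and 5 females). Its male and female means were 13.77 and 12.24 in Caspers Wilderness and 11.50 and 10.36 in N. lepida. In Palm Springs the males were at 12.97 and 13.02 and the female mean was 11.47. At an unadjusted limma p under 0.05 there were 858 probes. No probe passed without Caspers Wilderness replicate 1, Palm Springs replicate 3 or 4, or N. lepida replicate 1 or 2, and 2 passed without Caspers Wilderness replicate 3 or without Palm Springs replicate 2.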

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

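The patterns weighed here were noticed in the data, and the tests of array batches, of the floor for the species difference, of the Palm Springs position and of its spike-ins were chosen after related values had been seen. The bounds for the slopes and for catalogue probes were set before those values were computed, with related values already seen. The regroupings of arrays for probe counts were set down before their results.

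Chance division of the animals was tested by regrouping arrays. For the species comparison, 1 of 100 drawn splits, the real one, gave 1787 probes or more, and the highest other gave 4. For N. lepida against Caspers Wilderness, 1 of the 35 splits gave as many as 1852, and the highest other gave 189. For N. lepida against Palm Springs, 1 of 35 gave as many as 1095 (highest other 1), and for the N. bryanti populations 1 of 35 gave as many as 599 (highest other 1). For sex, 2 of 100 reassignments within populations gave as many as the 1 probe called, the real one included, and the highest other was 1. Chance division can be excluded at the 5% level for each of the counts between groups. The sex count also lies under that level, but it rests on 1 called probe. That call was lost on leaving out any 1 of 5 of the 12 animals, so it is not treated as settled. The splits regrouped single animals, so the species count shows only that the animals were not interchangeable. It does not show that N. lepida stands further apart than another of the groups would.

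Spike-in controls, which no comparison of the report used as expression, separated the N. lepida arrays on 5 of 5 steps, which are not independent of each other. This is what a difference between array batches, in labelling, hybridisation or spike-in lot, would give, and such a batch may contribute to the differences between N. lepida and N. bryanti. Unequal floors alone are argued against, since 84.2% of the species calls remained with a common floor. A batch and a species difference cannot be told apart, because every N. lepida array lies on one side. Species and population of origin are joined in the same way.

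Palm Springs had an intermediate slope between Caspers Wilderness and N. lepida. Sharing of Caspers Wilderness arrays is argued against by the slope of 0.441 with separate arrays. Separate arrays do not remove a property of the Caspers Wilderness group itself, which enters both differences. With values raised to the common floor, the raised floor of Caspers Wilderness replicate 3 is argued against by a slope of 0.408 without that array. In those values the low end had already been raised on every array, so this cannot decide for the slope without the common floor. That slope was 0.300, with replicate 3 itself at 0.331. The batch seen in the spike-ins stays open: the Palm Springs spike-in steps stood at 0.0028 ± 0.060 (SD, n = 4) of the way from Caspers Wilderness to N. lepida, but single steps ranged from -0.398 to 0.438 (SD 0.298 over the 5 steps). By the bound first set, which used the spread between animals alone, this batch would have been argued against; the spread between steps was brought in after both values had been seen. Such a batch may contribute and cannot be told apart from a property of the Palm Springs population, which was not tested.

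Catalogue probes were mostly lower in N. lepida. Unequal floors are argued against: above the common floor, 79.4% of the called catalogue probes were still lower, against 44.6% of custom probes. A general difference in how these probes hybridise to N. lepida RNA would give a shift in every N. lepida animal, and the median of catalogue minus custom probes was -0.25 ± 0.08 (SD, n = 4), below 0 in 4 of 4. The same measure between the N. bryanti populations was 0.04 ± 0.03 (SD, n = 4). A sequence difference under the probes is a possible explanation, but a batch that acts on probe types would give the same, and both stay open. Nor can these values set either apart from lower expression of the genes measured. Catalogue probes were also dimmer, at a median level of 5.49 against 9.54 to 11.46 in the custom families. The split was not confined to them: above the floor, 67.8% of the called probes of custom family PI426386924 were lower in N. lepida. In the remaining custom families the share was 34.2% to 41.6%.

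Single animals far from the other 3 of their group were found in 8 of 48 sets of 4 values examined, where chance gives about 1 in 20, or 2.4. In Caspers Wilderness, replicate 3 stood apart in its 5th percentile (gap over range 0.898), its mean correlation with the group (0.943) and its share of probes above the floor (0.897), which are not independent measures. The median of a class of control rows (ETG) was 5.78 in this array and at most 1.65 in the other Caspers Wilderness arrays. In Caspers Wilderness, replicate 1, the only female, stood apart at CUST_203_PI426384047 (0.896) and at the sex probe CUST_295_PI426395977 (0.835). The sex probe was named because the sexes differed there, so its flag follows from that choice. In Palm Springs, replicate 4 stood apart at CUST_60_PI426383273 (0.962), replicate 3 at CUST_347_PI426386924 (0.884) and replicate 1 at CUST_870_PI426386924 (0.892). The sex difference itself differed between populations at 3 probes by an interaction test in limma (adjusted p under 0.05). At an unadjusted limma p under 0.05 there were 520 of 6918, where chance gives about 1 in 20. The Caspers Wilderness sex difference in this test rests on the only female. An interaction there cannot be told apart from a trait of that animal, and the 3 probes were not examined singly.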

How the results depend on the processing

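The common floor and the fit without the 3 arrays of raised low end were chosen after the data had been seen. Under the settings fixed before the data were examined, counts and distances mostly held: 107 values stayed within 1.5 times (counts) or on their side of the threshold (distances) and 22 counts moved. For named probes, 306 stayed past the threshold and 25 did not, and none changed sign. The named probes of the group comparisons were chosen for animals that did not overlap, so leaving out animals could not change a sign. For a pair of groups, leaving out an animal of the remaining group left the difference itself unchanged. These values are therefore a weak check of the named probes. Males only lost 8 of the named calls, with fewer animals, and leaving out the 3 arrays of raised low end lost 4. A 2-fold minimum left 525 probes for the species comparison, 748 for N. lepida against Caspers Wilderness, 399 for N. lepida against Palm Springs and 292 for the N. bryanti populations, by construction. Males only gave 756, 992, 1.2e+02 (44 higher and 79 lower) and 72 in the same order, with fewer animals. Without the 3 arrays of raised low end the counts were 807, 903 and 578 for the comparisons with N. lepida, with fewer animals, and 0 for sex (797 at an unadjusted limma p under 0.05). Array weights gave 980 probes for the N. bryanti populations; the cause was not tested. Leaving out 1 animal gave 1245 to 2007, 1388 to 1837, 644 to 1304 and 375 to 598 probes in the same order, and 0 to 2 for sex. Without a population term no probe passed for sex (416 at an unadjusted limma p under 0.05); the cause was not tested. Distances kept their direction and an exact p under 0.05 under every alternative run. Tests on genes, other probes of a gene and gene lists were not run because the files do not pair names with probes. Signal over background limits the dim probes, whose low ends differ between arrays.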

Other observations

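With values below the common floor raised to it, the Palm Springs animals held different levels at several probes where the other groups were uniform. On these values, at 17 probes, Caspers Wilderness and N. lepida each varied by less than 2-fold but lay at least 8-fold apart, and the Palm Springs animals varied at least 4-fold at 9 of these. Among 5489 probes at which the outer groups were uniform and less than 2-fold apart, Palm Springs varied at least 4-fold at 25 (Fisher's exact test, p = 9.69e-17; probes are not independent). That background takes in probes wholly below the floor, which cannot vary once raised to it, so no conclusion is drawn from this p. The remaining group varied at least 4-fold at 2 of 9 probes in the other pairings of groups. This does not differ past the threshold from the 9 of 17 in Palm Springs (Fisher's exact test, p = 0.217). At the 9 divided probes, all 4 Palm Springs animals held an N. lepida-like level (over 0.75 of the way from Caspers Wilderness) at some and a Caspers Wilderness-like level (under 0.25) at others: replicate 1 at 3 and 6, replicate 2 at 4 and 4, replicate 3 at 6 and 3, and replicate 4 at 6 and 2. These probes were chosen for a wide range among the Palm Springs animals, so that each animal holds both levels is largely set by the choice. Over all probes with this floor, a range of at least 8-fold within the group was found at 74 in Palm Springs, 48 in Caspers Wilderness and 25 in N. lepida. Without it the order changed, with 121, 655 and 118, and the Caspers Wilderness group holds the array of highest low end. Also without the floor, 10 probes were uniform in the outer groups and at least 8-fold apart, and Palm Springs varied at least 4-fold at 4 of these and at 19 of 3803 probes of the background set. These comparisons were made after the values had been seen.

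The third principal component with the common floor (8.93% of the variance) followed sex within populations, with a mean male minus female score of -18.4 (two-sided exact permutation p = 0.00694, the smallest that 144 assignments can give). Palm Springs carried most of it, with males at -21.4 and -20.5 and females at 14.0 and 16.6. In N. lepida the males were at 0.0011 and -0.761 and the females at 5.56 and 2.66, and in Caspers Wilderness the female was at 11.8 and the males between -7.31 and 0.735. The relation was noticed before it was tested.

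Neighbouring probe numbers moved together most in the custom family PI426386924. There, the differences of 603 neighbouring pairs above the floor had a Spearman rho across probes of 0.504 for N. lepida against Caspers Wilderness and 0.516 for Palm Springs against Caspers Wilderness (permutation p = 0.000999 each, adjusted p = 0.00333, the smallest that 1000 shuffles can give). In the other 3 custom families the values were between -0.000978 and 0.0813. The highest of these, in PI426383273 for Palm Springs against Caspers Wilderness, also passed (adjusted p = 0.00333).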
